A study of Bos taurus with 2 samples.

How the data were processed

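RNA from 2 fractions of bovine whey, the pellet of a spin at 10000 g and the supernatant above it, was measured on 1 array each. Per the labels' protocols, RNA of 3 Holstein raw milk samples was mixed equally before labelling, so the 2 arrays hold pools and there are no replicates. Labelled copy RNA was made from 100 ng with a low-input Cy3 kit. The arrays are 1-colour Agilent bovine arrays read with Agilent Feature Extraction 10.7.3.1, per the file headers, with probe coordinates in build HGSC Btau_3.1. Both arrays lie on the same slide and scan, so the fractions do not differ in slide.

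The intensity values deposited by the authors are the scanner software's processed signals, background-subtracted and detrended within each array and not scaled between arrays, per the file headers. The log2 values of the authors' deposited table equal the log2 of those signals within 0.001 for all 43603 probes with a single spot on each array, with column medians of 4.81 for exosome and 1.32 for supernatant, so they are not scaled or centred. The scanner software's flags for outlier spots, saturation and signal above background were used as deposited. Other steps by the authors are not given in the sources used here.

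Control spots and 5 outlier spots on the exosome array and 2 on the supernatant array were left out, and spots of 1 probe were averaged, which left 43652 probes. No spot was saturated. Each array was put on a log2 scale and its 75th percentile over all non-control probes was subtracted. A probe counted as detected where the software called it well above background, and a gene where any of its probes was. The lowest signal with that call was 11.3 on the exosome array and 8.75 on the supernatant array. A gene's difference is the mean over its probes detected on both arrays. In 66 of the 3436 genes detected on both, different probes gave the detection, and those have no difference. Genes not well above background on 1 array have a bound, written as at least N-fold, from the brighter signal over the higher of the dim signal and the lowest well-above-background signal of that array, averaged over the gene's probes detected on the brighter array. An earlier form averaged all probes of a gene, also undetected ones, and took RPS9, ATP5MG and LIPH among the largest bounds in place of RPS14, RPL28 and LIX1. The array scaling uses a percentile that lies below the lowest well-above-background signal on the supernatant array. Differences are therefore also given before scaling and relative to the median gene measured on both.

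Gene symbols are those of the array's files. The accession of 26739 probes was in the reference gene table of assembly ARS-UCD2.0, which updated the symbol of 2347 probes, and the file's name was kept otherwise. That left 33321 probes with 1 gene symbol and 10331 unnamed. The table served for names only, none of its coordinates is printed, and whether a probe lies in an exon, intron or untranslated region was not analysed here.

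With 1 array per fraction no test was run and no p-value is given. The number of arrays limits the precision. The technical spread comes from 50 probes printed on 4 spots, of which 9 were well above background on both arrays. The size call was 2-fold. For each of 25 gene lists the median difference relative to the median gene was placed among 10000 random lists of the same size drawn within 20 bins of signal, which describes these 2 arrays. The draw was from all measured genes, the list's own members included. Random lists matched on exosome signal alone were added after the data were seen. Lists with fewer than 5 measured genes have only their members' values. The calculation was tested on simulated data for this comparison with 3370 genes and a spot noise of 0.2: of 50 genes each, 98% and 96% were recovered at 1.5 and -1.5, all 100% at 3 and -3, and 0.095% of 3170 unchanged genes were called. Both simulated arrays had the same probe levels apart from a constant, noise and the changes put in. The simulation therefore checks the arithmetic and not the scaling or the calls on the real arrays, whose levels differed widely.

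The rule for named genes was set before the data were examined. It takes the 8 genes furthest to each side among the 843 genes with all probes detected on both arrays and of the same sign, the 4 genes with the largest bounds in each direction, every measured major milk protein, up to 4 genes from each other list (the 2 highest and the 2 lowest measured on both), and CD9, CD63, CD81, GAPDH and ACTB. A few genes that this rule takes are not reported here. The lists and the alternatives were also set then. The alternatives were other scalings (75th percentile over probes detected on both, median, quantile, none, spike-in probes), normexp background correction with an offset of 50, a weaker, a stricter and no filter on dim probes (the stricter one at 4 times the lowest detected signal), the brightest probe per gene, outlier spots kept, and the authors' deposited table. Without a filter on dim probes, probes undetected in the supernatant enter with a signal that is not well above background there, so their differences mostly follow the exosome signal. Leaving out probes with repeat sequence or C runs was added after the data were seen. Repeat probes are those aligned by BLAST over at least 25 bases at 80% identity, in opposite orientation, to probes of at least 3 other genes.

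Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, networkx 3.6.1, matplotlib 3.10.9, BLAST+ 2.17.0 and R 4.3.3 with limma 3.58.1.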

Results

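The series compared the messenger RNA content of 2 fractions of bovine milk whey, the liquid left after fat and casein are taken from milk. One fraction was the pellet of a spin at 10000 g for 90 min, which the submitters call exosome, meaning small membrane vesicles released by cells, and which was resuspended and spun again in 2 washes. The speed is as the labels give it and is lower than is usual for pelleting small vesicles, and whether it was recorded correctly is not settled here, so what the pellet and the supernatant each hold is uncertain. The other was the supernatant above that pellet. RNA from 3 raw milk samples of Holstein cows was mixed in equal amounts, and 100 ng was labelled with Cy3, a green dye, for each fraction. Each pool was hybridised to 1 array of 43803 gene spots holding 60-base probes, so there were 2 arrays and 1 array per fraction. There are no replicates, so every difference below is between these 2 arrays and has no test. The only error that can be given is technical. The 50 probes printed on 4 spots each gave 9 that were well above background on both arrays, and their exosome-minus-supernatant difference varied between spots with an SD of 0.18 (log2). Different probes of 1 gene differed far more, with an SD of 1.71 (412 genes), so the spot SD understates the error of a gene's difference. The 2 arrays are too few to measure how much cows, milks or preparations vary.

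The first question was which transcripts were detected in each fraction. Far more genes were detected in the exosome pellet than in the supernatant. Of 15790 named genes, 3436 were detected on both arrays, 7502 only on the exosome array, 160 only on the supernatant array and 4692 on neither. Among genes of the lists set beforehand, 567 of 676 were detected in the exosome pellet and 268 in the supernatant. All of the 78 cytosolic ribosomal protein genes, 35 translation factor genes, 75 nuclear genes of oxidative phosphorylation, 37 proteasome genes and 41 genes of the endoplasmic reticulum and secretory pathway were detected in the exosome pellet. In the supernatant 94.9% of the ribosomal protein genes were detected, against 48.0% of the oxidative phosphorylation genes, 22.0% of the secretory pathway genes and 13.5% of the proteasome genes. At the level of probes, 25524 of 43652 (58.5%) were well above background on the exosome array and 5732 (13.1%) on the supernatant array. The supernatant counts, and with them the size of the contrast, depended on the detection rule. With the main rule 10938 genes were detected in the exosome pellet and 3596 in the supernatant. With the scanner software's weaker flag the counts were 13299 and 10461. When all probes of a gene had to be detected they were 7612 and 935.

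Before any scaling, probes measured on both arrays were mostly brighter in the exosome pellet. The median difference over 5305 probes well above background on both was 3.38 (log2), with quartiles of 1.43 and 5.82, and 7.86% of these probes were brighter in the supernatant. Over the 3370 genes measured by the same probe on both arrays the median difference was 3.50, an 11.3-fold higher exosome signal. The 8 spike-in control probes measured on both arrays, which report RNA added in known amounts during labelling, were also brighter on the exosome array, by a median of 2.27 (4.82-fold). Their differences ran from 0.71, for the brightest of them (signals of 320653 and 195451), to 2.54, for the next brightest on the exosome array. Whether the brightest signals were compressed was not tested. Scaling each array to its 75th percentile moved every difference by 5.56. That percentile was a signal of 248 on the exosome array and 5.24 on the supernatant array. The latter lay below 8.75, the lowest well-above-background signal there, and above 4.32, the 99th percentile of its negative controls. With that scaling 610 genes were at least 2-fold higher in the exosome pellet and 2140 at least 2-fold higher in the supernatant, and the median gene stood at -2.06. The same counts were 2810 and 44 with no scaling, 1932 and 545 with scaling to the spike-ins, 1261 and 1234 with scaling to the array medians, 363 and 2476 with quantile normalization, and 1195 and 1208 with normexp background correction. The direction of the bulk of genes therefore depended on the scaling and on the background correction, and the differences below are given relative to the median gene measured on both arrays, a value that no constant scaling moves. Because the median gene was itself brighter in the exosome pellet before scaling, a value below 0 on this scale does not by itself mean a brighter supernatant.

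The difference followed the exosome signal closely. Part of this trend is built in, as the exosome signal is a term of the difference and measured genes had to be detected in the supernatant. From the 674 genes with the dimmest exosome signal to the 674 with the brightest, among those measured on both arrays, the median difference relative to the median gene went from -2.58 to 4.20, while the median supernatant signal went from 17.0 to 49.8. Genes bright in the exosome pellet therefore stood to its side in general, and the random lists below, matched on the mean signal of both arrays, do not remove this. Against random lists matched on exosome signal alone, a comparison chosen after the data were seen, the percentile was 99.96 for ribosomal proteins, 99.4 for oxidative phosphorylation, 98.0 for translation factors, 91.1 for milk proteins, 90.5 for the secretory pathway, 74.0 for milk fat, 50.2 for the proteasome, 35.1 for exosome cargo and 2.40 for innate defence. At like exosome signal these percentiles rank mainly how dim the supernatant signal was. The random lists matched on exosome signal had a median of 6.37 for the ribosomal proteins and 5.93 for the milk proteins. They were drawn from all measured genes in the same bins of exosome signal, the list's own members included. How much of either distance other genes of like brightness share therefore cannot be told from these medians.

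**Figure D1:**
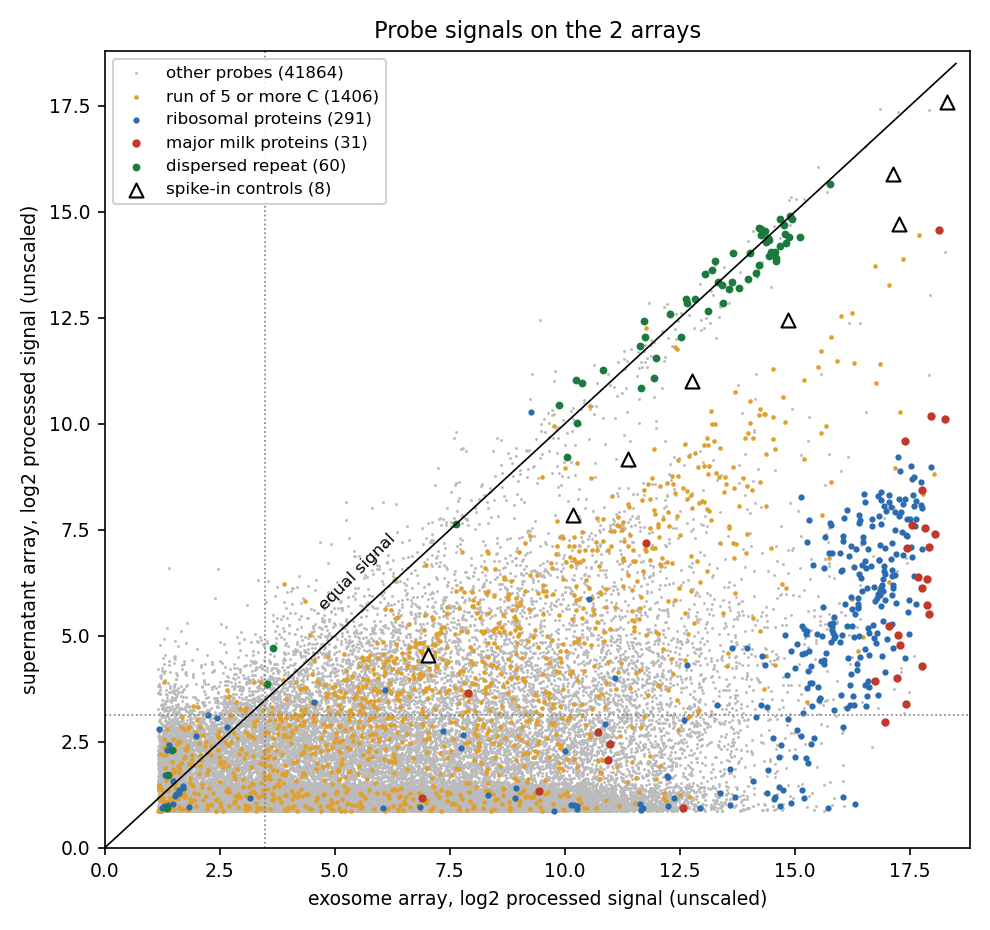
Log2 processed signal of each probe on the exosome array (x) and the supernatant array (y), both unscaled; the line marks equal signal, dotted lines mark the lowest signal well above background on each array, and triangles are the 8 spike-in controls measured on both. The milk protein and ribosomal protein genes measured on both arrays had median differences of 10.48 and 10.41 toward the lower right, and of 60 repeat probes 56 were above background on both arrays, 55 of them within 2-fold of equal signal.

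Transcripts of the major milk proteins, the caseins and whey proteins that mammary epithelium secretes, stood far to the exosome side. Of 12 on the array, 8 were measured on both arrays and 4 only on the exosome array. All 8 were at least 2-fold above the median gene, with a list median of 6.97 (log2) above it, at percentile 99.9 of random lists matched on signal. The caseins, which form the micelles of milk, were among them: CSN1S2 was 9.11 above the median gene, CSN3 7.72, CSN2 7.17 and CSN1S1 6.77. GLYCAM1, a mucin-like milk protein, was 7.58 above it. LALBA (alpha-lactalbumin, the regulatory subunit of lactose synthase) was 5.12 above it and PAEP (beta-lactoglobulin) 4.22. LPO, the antibacterial lactoperoxidase, was 1.07 above it. LPO was brighter in the exosome pellet before scaling by 4.57 and dimmer after 75th percentile scaling by a difference of -0.99, so its direction turned with the scaling. The unscaled exosome signal was 25538 to 246582 for the 7 genes other than LPO, against 28.8 to 1168 in the supernatant. SPP1 (osteopontin), MFGE8 (lactadherin), PIGR and FOLR1 were detected in the exosome pellet alone, at unscaled levels at least 689-fold, 148-fold, 88.9-fold and 79.1-fold above the supernatant. After 75th percentile scaling these bounds were 14.57-fold, 3.13-fold, 1.88-fold and 1.67-fold, the last 2 under the 2-fold call.

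Different probes of a milk protein gene gave differences of different size. The 3 LALBA probes gave unscaled differences of 13.48, 8.13 and 4.25, of which the second lies on chromosome 5 at 34388762 to 34388821 in the Btau_3.1 build of the array's design, at position 650 of the transcript. The 3 PAEP probes gave 9.32, 10.30 and 3.55. The last of these lies on chromosome 11 at 107171376 to 107171429, at position 724, and had signals of 288102 and 24542. With the brightest probe per gene PAEP stood at -0.0013 against the median gene. The 5 CSN2 probes ranged from 9.21 to 12.81 and the 6 CSN1S1 probes from 7.76 to 12.50.

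Genes of milk fat and lactose synthesis were detected mainly in the exosome pellet, as were named genes in general (7502 there alone, 3436 on both arrays). Of 36 milk fat genes, 12 were measured on both arrays and 21 were detected in the exosome pellet alone. Of the 12, 6 were at least 2-fold above the median gene, 2 were at least 2-fold below it and 4 lay between. FABP3, a fatty acid carrier, was 10.12 above the median gene (4 probes, 2 of them measured on both), with unscaled signals of 181866 and 14.4. XDH, the xanthine oxidoreductase of the milk fat globule membrane, was 9.99 above it, a 1017-fold difference and the largest among the 843 genes whose probes were all measured on both arrays and agreed in sign. The XDH probe lies on chromosome 11 at 14805189 to 14805248. PLIN2, which coats lipid droplets, was detected in the exosome pellet alone, at least 302-fold higher after 75th percentile scaling and at least 14292-fold before it. INSIG1, by 1 of its 2 probes, stood at -3.77 against the median gene and FADS2 at -1.21. Without a filter on dim probes INSIG1 stood at 1.49, with its other probe entering at supernatant background. The list median was 1.81 above the median gene, at percentile 93.0 of matched random lists, 2.68 from 27 genes with the weaker detection flag, 4.71 from 36 genes without a filter on dim probes and -0.36 with the stricter filter, which left 1 gene. Of 10 lactose synthesis genes, 2 were measured on both arrays and 8 in the exosome pellet alone. B4GALT1, the catalytic subunit of lactose synthase, was 5.62 above the median gene and GALT 1.14.

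The protein synthesis machinery stood as far to the exosome side as the milk proteins. All 74 ribosomal protein genes measured on both arrays were at least 2-fold above the median gene, and 4 more were detected in the exosome pellet alone. Their median was 6.90 above the median gene, against 0.48 to 2.57 for the middle 95% of matched random lists. RPS27A was 8.92 above the median gene, RPL35 8.89, RPL29 4.70 and RPLP2 3.33. Of the RPLP2 probes, 4 gave unscaled differences from 8.35 to 9.92, and a probe made from an expressed sequence tag gave -1.01. The ribosomal genes RPS7 (8.72), RPL19 (8.48), RPS2 (8.27), RPL37 (8.20), RPL14 (7.94), RPL32 (7.91) and RPS3A (7.89) were, after XDH, the genes with the largest differences among those with all probes measured on both arrays. RPS14 and RPL28 were detected in the exosome pellet alone, each by 1 of 2 probes, at least 196-fold and 87.6-fold higher after 75th percentile scaling. All 14 translation factor genes measured on both arrays were at least 2-fold above the median gene, with a list median of 6.44. TPT1, a translationally controlled protein, was 9.04 above it, EEF1A1 (elongation factor) 7.68, EIF5 4.85 and EIF1 2.94. The EIF1 value is a mean of 2 probes at unscaled differences of 2.498 and 10.40, on opposite sides of the median gene.

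Among genes measured on both arrays, most other housekeeping groups lay on the same side by smaller amounts. The main list medians leave out the genes detected in the exosome pellet alone, so their sizes are not on an equal footing. Of 36 nuclear oxidative phosphorylation genes measured on both arrays, 32 were at least 2-fold above the median gene, 2 at least 2-fold below it and 2 between. ATP5F1A (7.64) and COX8A (6.76) were the highest, and UQCRB (-1.498) and NDUFA6 (-3.71) the lowest. UQCRB was measured on both arrays by 1 of 3 probes and NDUFA6 by 1 of 2, and without a filter on dim probes they stood at 4.93 and 2.91, on the other side of the median gene. Their other probes then entered with a supernatant signal that was not well above background. MPC1, the mitochondrial pyruvate carrier, was detected in the exosome pellet alone, at least 77.3-fold higher after 75th percentile scaling. The median of the oxidative phosphorylation list was 4.96. It was 5.59 from 63 genes with the weaker detection flag and 6.22 from 75 without a filter on dim probes. Of 11 genes encoded in mitochondrial DNA, 5 were detected in the exosome pellet alone, 5 on neither array and CYTB on both, at -2.15 against the median gene by 1 of its 5 probes and 0.23 without a filter on dim probes. The secretory pathway list had a median of 4.46 (9 of 41 genes measured on both, percentile 99.7). ATF4, a stress-response transcription factor, was 7.63 above the median gene and SSR2 6.80, and HYOU1 stood at -1.13 and DNAJB9 at 0.40. Of 37 proteasome genes, 32 were detected in the exosome pellet alone. The other 5 had a median of 2.71 (percentile 76.7 of matched random lists, and 4.87 from 25 genes with the weaker detection flag), with PSMB7 at 4.20, PSMD8 at 3.00, PSMD11 at 2.43 and PSMD12 at 1.71. Of 11 replication-dependent histone genes, 7 were detected in the exosome pellet alone and 2 on both arrays, H2AC14 at 4.10 and H2BC21 at 3.75.

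Transcripts of proteins that mark exosomes were detected mainly in the exosome pellet, as were named genes in general. Of all named genes, 7502 were detected on the exosome array alone, 3436 on both and 160 on the supernatant array alone. Of 28 genes for tetraspanins and exosome cargo, 16 were detected in the exosome pellet alone, 9 on both arrays and 3 on neither. Those 9 had a median of 2.08 above the median gene, at percentile 61.4, a value that leaves out the 16 genes below background in the supernatant. The median was 4.59 from 21 genes with the weaker detection flag and 4.06 from all 28 without a filter on dim probes. With the 25 genes detected in the exosome pellet at their measured difference, or at their bound where there was none, the unscaled median was 5.80 against 3.75 for all genes detected there. Of these 25 values 16 are bounds, which follow the exosome signal. Against random lists matched on exosome signal the 9 measured genes were at percentile 35.1. CD9, a tetraspanin, was 2.49 above the median gene by 1 of its 2 probes. The tetraspanin genes CD63 and CD81 were detected in the exosome pellet alone, at least 390-fold and 309-fold above the supernatant before scaling and 8.25-fold and 6.53-fold after it. HSP90AA1 (5.72) and the glycolytic enzyme GAPDH (4.89) were the highest, and ANXA11 (1.19) and FLOT2 (0.37, from 2 probes on opposite sides of the median gene) the lowest. ACTB, the cytoskeletal beta-actin, was 7.05 above the median gene by 1 of its 4 probes. Of 35 genes of the ESCRT machinery, which buds vesicles, and of vesicle release, 23 were detected in the exosome pellet alone and 11 measured on both, with a median of 0.80 at percentile 68.6 and 2.20 from 27 genes with the weaker detection flag, 3.90 from 35 genes without a filter and -3.36 from 3 genes with the stricter filter. VPS28 was at 4.59 and TSG101 at 3.79, while SMPD2 was at -2.17 and SMPD3, a neutral sphingomyelinase, at -3.72.

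**Figure D2:**
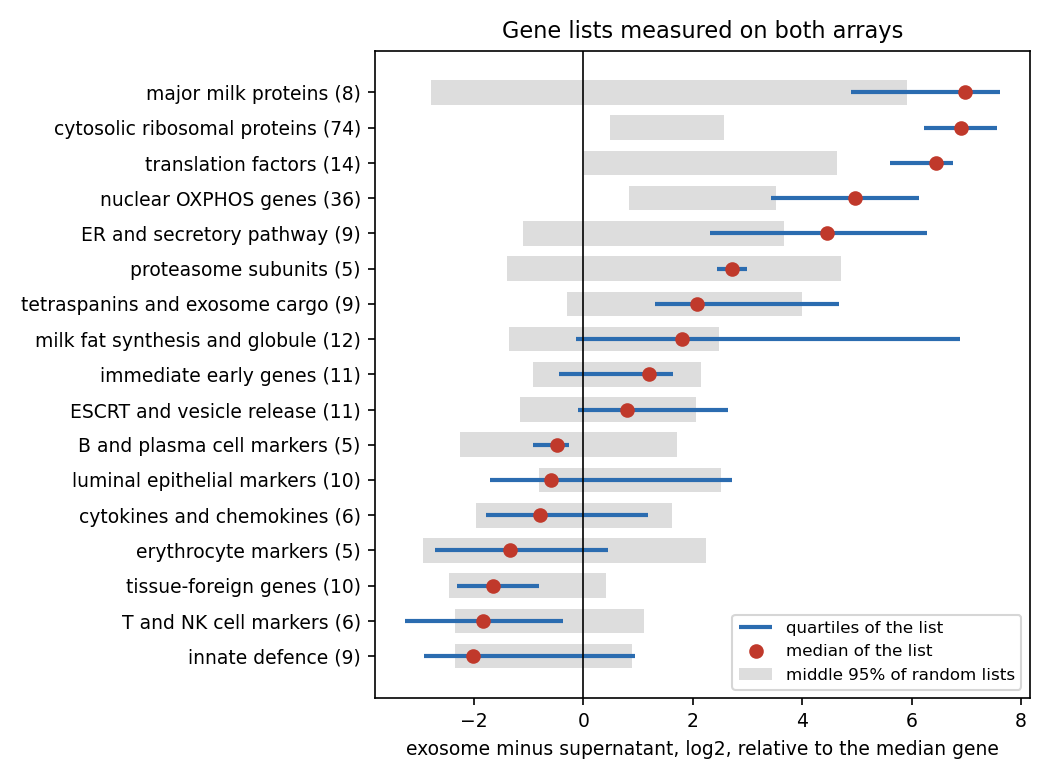
Median (point) and quartiles (line) of the exosome-minus-supernatant log2 difference for each list with at least 5 genes measured on both arrays, relative to the median gene, with the number of genes in parentheses. Grey bars give the middle 95% of 10000 random lists matched on signal. The medians of 5 lists lie above their bar, from 4.46 for the secretory pathway to 6.97 for the major milk proteins.

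Luminal markers of mammary epithelium were 95% detected on the exosome array and 50% on the supernatant array, against 33.3% to 73.3% and 23.1% to 46.2% for the lists of blood and stromal cells, with no test of the difference. Basal and myoepithelial markers had shares of 75% and 33.3%. Of all 15790 named genes, 10938 were detected on the exosome array and 3596 on the supernatant array. A list of genes typical of other tissues had shares of 41.2% and 21.6%. Of 20 luminal epithelial markers, 19 were detected in the exosome pellet and 10 in the supernatant. Those measured on both arrays had a median of -0.59 (percentile 4.18), with members on both sides, and 2.17 without a filter on dim probes. The luminal transcription factor ELF5 was 7.53 above the median gene and KRT19, a keratin, 5.82, while TFAP2A stood at -2.03 and ERBB3, a growth factor receptor, at -5.61. ERBB3 rested on 1 of 3 probes, and TFAP2A, by 1 of 2, was at 2.39 without a filter on dim probes. Of 12 basal and myoepithelial markers, 9 were detected in the exosome pellet and 4 in the supernatant: KRT14 (-0.38), ACTA2 (-2.54), MYH11 (-2.75) and MYLK (-5.02). Of 13 neutrophil markers, 8 were detected in the exosome pellet and 3 on both arrays, among them S100A12 (0.17) and MMP9 (-0.70). Monocyte and macrophage markers were detected in the exosome pellet for 11 of 15 genes, with CSF1R at -0.44, CD68 at -1.20, TYROBP at -1.36 and CD14 at -2.42, each of these last 2 by 1 probe and above the median gene, at 0.42 and 1.77, without a filter on dim probes. T and NK cell markers were detected there for 11 of 20 genes, and the 6 measured on both arrays had a median of -1.84 (percentile 7.73). CD2 was at 0.40, CD4 at -0.11, GZMA at -3.51 and CD3D, a T cell receptor chain, at -4.96. Of 12 B and plasma cell markers, 7 were detected in the exosome pellet and 5 in the supernatant. The 5 measured on both had a median of -0.48 (percentile 43.8), with PAX5 at 0.00, CD79A at -0.93 and JCHAIN at -2.96. Of 13 erythrocyte markers, 8 were detected in the exosome pellet and 6 in the supernatant. The 5 measured on both by the same probe had a median of -1.34 (percentile 33.3). HBA was at 0.86, HBQ1 at 0.45 and HBM at -3.11. Of 15 stromal and endothelial markers, 5 were detected in the exosome pellet. COL3A1, a fibrillar collagen, was at 3.15 by 1 of 10 probes and -2.06 without a filter on dim probes, COL1A1 at 0.75 and DCN at -2.06. The values of CD4, HBQ1 and COL1A1 are each a mean of 2 probes on opposite sides of the median gene.

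Immune and response lists lay on both sides of the median gene. The 9 innate defence genes measured on both arrays had a median of -2.02 (percentile 8.2), with 2 at least 2-fold above the median gene and 5 at least 2-fold below it. That median was 0.58 with the weaker detection flag, on the other side of the median gene. SAA3, an acute phase protein, was 4.66 above the median gene and RNASE4 1.12, while CATHL6 was at -2.99 and TLR2 at -3.26. Of 15 MHC genes, 13 were detected in the exosome pellet, and the 4 measured on both arrays were BOLA (0.31), BOLA-DOA (-0.86), TAP1 (-2.04) and BOLA-DQB (-2.13). The BOLA value is a mean of 3 probes that includes its repeat probe, at an unscaled difference of -0.57, and was 2.56 without repeat and C-run probes, a setting chosen after the data were seen. The 6 cytokines and chemokines measured on both had a median of -0.79 (percentile 25.6). That median was 0.07 without repeat and C-run probes. The chemokine CXCL10, by 1 of 3 probes, was at 4.06 and at -0.29 without a filter on dim probes. Others were TGFB2 at 1.56, CCL4 at -1.85 and IL1B at -2.45. The 11 immediate early genes had a median of 1.20 (percentile 72.7), with BTG2 at 2.52, DUSP1 at 2.36, EGR1 at -1.01 (0.19 with the weaker detection flag) and EGR2 at -1.87. With the stricter filter on dim probes that median was -0.33, from 6 genes. Of 51 genes typical of liver, muscle, brain, pancreas, testis or eye, set as a check on signal from transcripts foreign to milk, 21 were detected in the exosome pellet and 11 in the supernatant. The 10 measured on both had a median of -1.65 (percentile 22.6), with TAT at 0.68, APOA2 at 0.16, ARG1 at -3.06 and MYL1 at -3.48.

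Most genes detected on either array had only a bound, 7502 in the exosome pellet alone and 160 in the supernatant alone, against 3436 detected on both. Each gene detected in the exosome pellet was therefore also placed at its measured unscaled difference, or at its bound where no probe was above background on both arrays. A bound sets the supernatant at 8.75, its lowest well-above-background signal, unless the dim signal was higher. Bounds therefore follow the exosome signal, and lists with many bounds are placed largely by exosome brightness. Bounds stood for 32 of 37 proteasome genes, 32 of 41 secretory pathway genes and 16 of 25 exosome cargo genes. The median over all genes detected in the exosome pellet was 3.75 (log2). It was 10.48 for ribosomal proteins, 9.03 for milk proteins, 8.96 for translation factors, 8.51 for oxidative phosphorylation genes, 7.58 for proteasome genes, 6.35 for milk fat genes, 6.29 for the secretory pathway and 5.80 for tetraspanins and exosome cargo. It was 5.25 for lactose synthesis, 5.04 for ESCRT and vesicle release genes, 4.71 for immediate early genes, 4.26 for histones, 4.24 for the 5 stromal markers detected and 3.95 for luminal markers. Innate defence genes were at 3.34, neutrophil markers at 2.67, erythrocyte markers at 2.63, B and plasma cell markers at 2.58, mitochondrially encoded genes at 2.49, MHC genes at 2.35, tissue-foreign genes at 2.30, cytokines at 2.17, monocyte and macrophage markers at 2.14, basal markers at 1.45 and T and NK cell markers at 1.44.

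Few genes were brighter in the supernatant before scaling, 44 of them by at least 2-fold. The 8 genes furthest to that side among those with all probes measured on both arrays were STAC3, TMEM107, INSYN1, LRRC30, MYLK, USP50, GPR171 and RAB6B. Their unscaled differences ran from -2.40 for STAC3, an adaptor of skeletal muscle, to -1.45 for RAB6B, that is 5.28-fold to 2.74-fold brighter in the supernatant, and relative to the median gene from -5.91 to -4.96. STAC3 had signals of 13.4 and 70.6, on chromosome 5 at 60710602 to 60710661, and MYLK (myosin light chain kinase) 42.7 and 122 by 2 probes. All but MYLK were measured by 1 probe. The probes of TMEM107, INSYN1 and LRRC30 aligned to probes of 2, 1 and 1 other genes over at least 25 bases. Genes detected in the supernatant alone were dim. TRIM31, a ubiquitin ligase, had a supernatant signal of 95.6 and was at least 8.48-fold higher there before scaling and 401-fold after 75th percentile scaling. SCN2B, LIX1 (by 1 of 2 probes) and VSTM2L were at least 4.70-fold, 3.48-fold and 3.45-fold higher before scaling.

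The sequence of the probes bore on these values. A set of 60 probes aligned in opposite orientation to probes of at least 3 other genes, as dispersed repeats in transcripts do, while 4 reversed sequences met the same rule. Of these 60, 57 were well above background on the supernatant array and 56 on the exosome array, and the 56 measured on both had a median unscaled difference of 0.09, against 3.41 for other probes. They held 25.7% of the total supernatant signal and 1.27% of the exosome signal. BOLA and CHMP1B, an ESCRT gene picked after its values were seen, each have 1 such probe, and the probes behind the values of TLR2, ARG1 and CD3D aligned to probes of 4, 4 and 2 other genes, with no other probe of ARG1 or CD3D above background on either array. The extent depended on the rule. With at least 1 other gene in place of 3, 393 probes met it. Of these, 166 were measured on both arrays, with a median unscaled difference of 0.34, and 120 lay within 2-fold of equal signal. The setting without repeat probes leaves out only those that meet the rule of 3. Probes with a run of 5 or more C were detected more often than others, and 1 or more such probes belong to CSN2, MFGE8, GALT, KRT19, TYROBP, HBA, RPL29, PSMB7, PSMD8, ATF4, SSR2, ANXA11 and BOLA-DOA among the genes named above. The share of probes well above background went from 8.48% for a longest C run of 1 to 49.2% for 6 or more on the supernatant array, and from 58.5% to 83.3% on the exosome array.

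**Figure D3:**
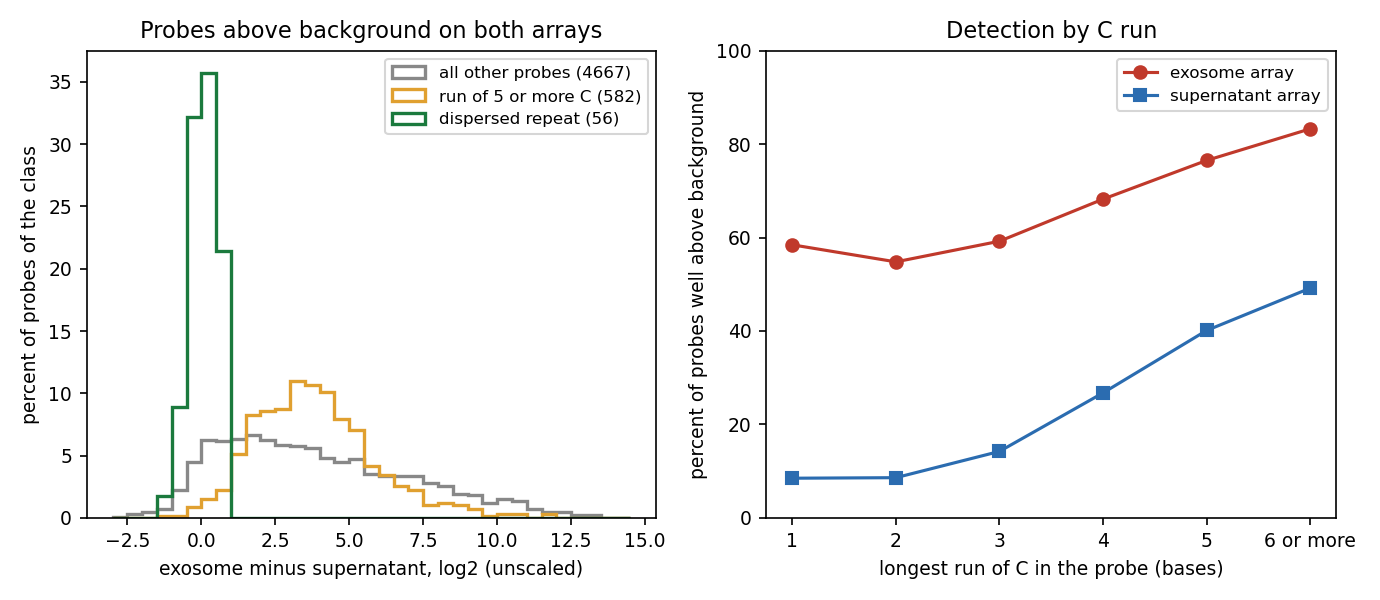
Left, distribution of the unscaled exosome-minus-supernatant log2 difference over probes well above background on both arrays, for 56 repeat probes, 582 probes with a run of 5 or more C and 4667 others, in percent of each class. Right, percent of probes well above background on each array by the longest run of C, from 8.48% to 49.2% on the supernatant array and 58.5% to 83.3% on the exosome array.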

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

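All 7 tests reported here were chosen after the results were seen, and 5 of them replaced a first form whose outcome had also been seen, given beside them below. A control probe of the exosome array meant to stay silent, ETG10_13482, had a median signal of 21.6 over 10 spots (SD 10.3), above 7.85, the 99th percentile of the negative controls. It was 2.55 on the supernatant array. It was picked out as signal in data that no comparison uses, among 25 such control probes per array, and it lay below the brightest negative control spot.

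Far fewer probes were above background on the supernatant array. If its labelling or hybridisation had only been weaker, nearly all probes bright enough on the exosome array to survive the largest spike-in drop with 1 log2 unit to spare should be detected, but 22.9% of 14450 were (first form: milk protein genes differed by 6.76 log2 units more than the spike-ins). Whether exosomes left in the supernatant were its only source stays open: 58.6% of 2819 genes lay below the lowest milk protein gene by more than the spot error (first form: 92.1% lay over 2 log2 units below the milk protein median), but probes of 1 gene differed with an SD of 1.71 (log2, 412 genes), so unequal ratios decide nothing. Fragmented RNA read near the 3′ end would favour 3′ probes, and at equal exosome signal these were detected more often by 2.06 percentage points (interval 0.41 to 3.74, 3905 transcripts), while 19.0% against 10.8% were detected before matching (first form: the exosome excess was larger at the 3′ end by 0.83, interval 0.15 to 1.40, 171 transcripts). The amount of the supernatant RNA, its quality apart from this 3′ comparison and the fraction itself also stay open and were not tested.

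Before scaling, probes with dispersed repeat sequence were equally bright on both arrays, while the spike-ins were brighter on the exosome array by 2.27 (log2). Transcripts of the genes they are named for would also light the same genes' other probes, but 18.9% of 53 other probes that align to no other gene were detected in the supernatant, against 95% of the 60 repeat probes (first form, with all 89 other probes: 40.4%). Binding through GC content would give 11.6% detected at equal GC content (first form: 0 of the 60 have a C run). Repeat-bearing RNA from many loci may be the source, and DNA carried into the labelling stays equally open, as neither was tested. No biological explanation was tested.

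Probes with runs of C were detected more often in the supernatant. Within 771 genes the C-run probes were above background more often than other probes of the same gene by 27.8 percentage points (interval 23.9 to 31.5), which goes against transcripts of GC-rich genes as the cause. At equal GC content the excess was 25.9 points (interval 23.4 to 28.3), which goes against GC content alone. Probes with runs of G were also above their GC-matched level, at 37.4% against 15.0%, so binding of label by such runs may contribute. No biological explanation was tested.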

How the results depend on the processing

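The alternatives were set before the data were examined, except leaving out repeat and C-run probes, which was chosen after seeing the data. No paired analysis was possible because each fraction has 1 array and no test was run. Signal near background on the supernatant array limits many of the gene differences. In particular, values without a filter on dim probes include probes whose supernatant signal is background. The cause of each difference between settings was not tested, except where fewer or more genes enter by construction. Keeping outlier spots and scaling to probes detected on both arrays moved none of the list medians and none of the named genes beyond the spot error, and constant scalings moved no list median. The ribosomal protein median ranged from 6.49 (brightest probe) to 7.14 over 13 alternatives. Constant scalings and the authors' unscaled table are among these and could not move it, as it is taken relative to the median gene.

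The median difference turned from -2.06 to 0.013 with median scaling, 3.50 with no scaling and with the authors' table, and 1.55 with spike-in scaling, and was -2.73 with quantile normalization, -0.049 with normexp and -2.65 without a filter. Genes 2-fold higher in exosome and in supernatant numbered 1261 and 1234 (median), 2810 and 44 (none, and the authors' table), 1932 and 545 (spike-ins), 1195 and 1208 (normexp), 1813 and 6005 (weaker filter), 2809 and 10297 (no filter) and 200 and 879 (stricter filter), and 363 were higher in exosome with quantile normalization. On the supernatant array 20268 probes and 10461 genes were detected with the weaker flag, 2050 and 1368 with the stricter filter, and 935 genes with all probes required. For list genes these were 526, 155 and 74.

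List medians with quantile normalization were 8.26 for milk proteins, -1.02 for T and NK cells, -0.68 for erythrocytes, 6.03 for translation factors, 4.53 for oxidative phosphorylation, 2.36 for the proteasome, -1.31 for innate defence and -0.33 for cytokines. With normexp they were 7.52 for milk proteins, -1.48 for T and NK cells, 3.49 for the secretory pathway, 0.43 for ESCRT, -1.57 for innate defence, 0.56 for immediate early genes and -1.20 for tissue-foreign genes. With the weaker filter they were 6.08 for milk proteins, 2.68 for milk fat, -2.26 for T and NK cells, -1.77 for erythrocytes, 5.83 for translation factors, 5.59 for oxidative phosphorylation, 4.87 for the proteasome, 3.73 for the secretory pathway, 4.59 for exosome cargo, 2.20 for ESCRT, 0.73 for immediate early genes and, reversed, 0.58 for innate defence. Without a filter they were 6.54 for milk proteins, 4.71 for milk fat, 2.17 for luminal markers, -2.38 for T and NK cells, -1.81 for B cells, -2.40 for erythrocytes, 6.22 for oxidative phosphorylation, 5.27 for the proteasome, 4.06 for exosome cargo, 3.90 for ESCRT, -0.34 for innate defence and -2.43 for tissue-foreign genes. With the stricter filter they were 6.601 for milk proteins, 6.82 for translation factors, 3.63 for oxidative phosphorylation and 1.51 for exosome cargo. Fewer than 5 genes stood behind the values for T and NK cells (-3.39, 3 genes), erythrocytes (-0.054, 3 genes) and the secretory pathway (2.43, 2 genes). The same held for ESCRT (-3.36, 3 genes), innate defence (-2.80, 3 genes) and cytokines (-2.35, 1 gene). Reversed were -0.36 for milk fat (1 gene) and -0.33 for immediate early genes (6 genes). With the brightest probe they were 5.12 for milk proteins and 6.49 for ribosomal proteins. Without repeat and C-run probes they were -1.98 for erythrocytes, -1.11 for innate defence and 0.071 for cytokines. Reversed here marks a change of sign from a main median past the 2-fold call. Smaller main medians also changed sign, for ESCRT with the stricter filter, luminal markers without a filter and cytokines without repeat and C-run probes.

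Named genes that reversed were CD14 (1.27), COL3A1 (-0.11) and EGR1 (0.19) with the weaker filter, PAEP (-0.0013) with the brightest probe, and, without a filter, INSIG1 (1.49), TFAP2A (2.39), CD14 (1.77), TYROBP (0.42), COL3A1 (-2.06), CYTB (0.23), NDUFA6 (2.91), UQCRB (4.93) and CXCL10 (-0.29). Among the other values for named genes, 1082 stayed within the spot error and 378 moved beyond it without a change of sign in a value past the size call.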

Other observations

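The comparisons in this part were all chosen after the values were seen. Among the brightest supernatant probes, 225 exceeded a signal of 1000, and 164 of them (72.9%) were within 2-fold of their exosome signal before scaling. Of the 225, 53 were repeat probes, 34 had a run of 5 or more C and 3 belonged to major milk protein genes. The BOLA repeat probe differed by -0.57 between the arrays, while the same gene's other probes stood at 5.78 with undetected ones at their bound. The corresponding values were 0.03 and 4.47 for CHMP1B, 0.09 and 6.34 for NIPSNAP1, 0.29 and 6.197 for GTF2H5 and 0.43 and 4.08 for POLH. These 5 have the largest gaps among 23 genes, whose median gap was 1.18 (quartiles 0.15 and 2.65). The gap was 0.09 for ACOT11, -0.07 for MTMR2, -0.50 for IL1RL1, -0.75 for SP140L and -0.89 for SLC5A12.

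Repeat probes that align to each other fell into families with probes of both orientations. In the larger family, 14 probes of 1 orientation had a median unscaled difference of 0.46 (0.25 to 0.58) and 14 of the other -0.16 (-0.59 to 0.10). In the smaller family the medians were 0.61 for 7 probes and -0.42 for 6. The ranges of the orientations did not overlap in either family.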
